A study of Mus musculus with 21 samples.

How the data were processed

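Total RNA of whole liver lysates from 21 mice, 11 controls and 10 with Gata4 deleted through a Clec4g-driven Cre, was biotin-labelled and hybridised to Affymetrix arrays, per the labels' protocols. The labels name a standard diet and give no sex or age. The deposited table held log2 values made with RMA by the authors, per the submitters' processing notes; RMA corrects background, normalises the arrays to a common distribution by quantiles and summarises the probes of a gene. The version of RMA, the array type and the genome build were not given in the sources used here. All 21 columns held the same sorted values to within 0.0019, with quartiles of 2.98 and 6.12. Scanner files were not used here, so background and probe-level signal could not be weighed, and low values can be close to background. The values of control replicate 1 carried finer decimals than those of the other 20 arrays, for which no reason was given in the sources used here.

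Each of the 25428 rows was 1 Entrez gene number followed by a suffix, so no gene had several rows to combine. Symbols came from the platform annotation paired with the table: 24705 rows had 1 symbol, 723 had none there and stayed unnamed, none had several, and 1 symbol stood on 2 rows. All rows were tested without a filter; 51 of the 1864 genes past the threshold were unnamed. Gene order for the neighbours of a gene came from the RefSeq annotation of assembly GRCm38.p6, used only for order, and no coordinates were taken from it because the build of the array was not given.

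Genotype was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values, with genotype and number run as terms over all 21 arrays and Benjamini-Hochberg adjustment over all genes; a gene passed at an adjusted p under 0.05. Number runs are the 2 runs of consecutive sample numbers in the descriptions; the labels do not call them batches. A fit with a genotype by run term tested whether the difference changed between runs. Differences are knockout minus control on the log2 scale, with the standard error of the fit, and group values are means with SD over animals. Labels call the samples biological replicates, and controls siblings, so each array was taken as 1 animal.

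Gene lists for 28 cell types and pathways of the liver were fixed from textbook knowledge; 602 of their 655 distinct symbols were measured, and the lists overlap (627 measured entries). Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with the rotation test fry as alternatives, all adjusted over the 28 lists. Camera compares a list with the other genes; fry asks whether its genes move one way on balance, and its mixed form whether they change in either direction. A list score per liver is the mean over its genes of the log2 value minus the control mean of the same run. The fry test passed 16 lists and its mixed form 27.

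The genes named were set by rule: Gata4 and Clec4g; the 10 largest rises and 10 largest falls among genes past the threshold with 1 direction in both runs, without predicted genes; and from each list up to 3 members with the lowest adjusted p that passed over all genes or over the list alone, or else the 1 with the lowest p. This gave 81 genes. The groups, tests, lists, naming rule and processing alternatives were fixed before the data were examined, except an alternative without the 2 arrays that correlated least with their group, which was added after seeing the data. The family test and the tests of genes around Clec4g, among them a comparison of Trappc5 with neutrophil markers per liver by the exact signed-rank interval, were also added later.

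Alternatives were the fit without the run term, within each run, with the replicate number as a block, after a second quantile normalization, after median centring, without genes of mean under the median, with an intensity trend and robust prior, with array weights, and without each array in turn. Outlying values were looked for with Dixon's ratio in the knockout group of 10; the control group of 11 was not tested. The count of genes past each threshold was set against 100 splits of the arrays into groups of the same sizes, the real one included. Families of genes sharing a symbol stem, with at least 15 members, were tested with Fisher's exact test over 155 families in both directions. Correlations across livers were computed on run-centred values with 100000 permutations.

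The procedure was tested on simulated data with the means, spreads and run differences of the real arrays: of 100 genes given a log2 change of 0.5 it recovered 83%, of 100 given a change of 1 it recovered 98%, with 11 false calls among 25428 genes, and it passed the 1 gene list that was moved and none of the 27 others. Simulated genes varied independently, so that check does not cover correlated lists. Figures were drawn with matplotlib 3.10.9.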

Results

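Whole livers of 21 mice were profiled on Affymetrix expression arrays, 1 array per animal. In 10 mice the transcription factor gene Gata4, flanked by loxP sites, was crossed with a Cre driver under Clec4g regulatory sequence, which is active in the sinusoidal endothelium of the liver; these are called knockout livers here. The other 11 livers came from control siblings, and whether these carried the driver was not given in the sources used here. The sample descriptions carry numbers that fall into 2 runs of consecutive values, with 5 control and 4 knockout livers in run 1 and 6 control and 6 knockout livers in run 2, so each run held both genotypes and run was a term in the fit over all livers. The values were log2 RMA signals for 25428 genes, with a median of 3.75 on every array and the same distribution on each. The median standard error of a genotype difference over all genes was 0.078 on the log2 scale.

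The comparison of the genotypes addressed how loss of an endothelial transcription factor alters the liver as a whole. Knockout livers had more transcript of lipoprotein lipase (Lpl, which releases fatty acids from circulating triglyceride), of the guidance receptor Robo1, of the desaturase Scd2 and of immunoglobulin genes, and less of the fatty acid hydroxylases Cyp4a14 and Cyp4a10 and of the sulfotransferases Sult2a3, Sult2a8 and Sult2a5. As lists, markers of continuous capillaries, monocytes and B cells were higher. Lists of sinusoidal endothelial, matrix and Kupffer cell genes passed with a preset correlation among genes and in the rotation test fry, but not with an estimated correlation (adjusted p = 0.12, 0.13 and 0.13 with an estimated correlation). Lpl was 9.72-fold higher, with a log2 value of 5.88 ± 0.85 (SD, n = 11) in controls and 9.14 ± 1.22 (SD, n = 10) in knockout livers. At an adjusted p below the threshold of 0.05, 834 genes were higher and 1030 lower, 7.33% of those measured, and 122 of the higher but 25 of the lower genes changed by more than 2-fold. The lower genes numbered 629 without control replicate 8 and 661 without control replicate 9. The first principal component, with 22.1% of the variance, placed all knockout livers above all controls (lowest knockout -0.69, highest control -2.97).

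The deleted gene itself was a weak guide in whole liver. Gata4 had a log2 value of 6.73 ± 0.29 (SD, n = 11) in controls and 6.53 ± 0.23 (SD, n = 10) in knockout livers, a difference of -0.19 ± 0.10 (SE) that did not pass the test (adjusted p = 0.26). It was -0.34 in run 1 and -0.08 in run 2, and 7 of 10 knockout livers lay below the control mean of their run. The positions of the Gata4 probes relative to the loxP sites were not given in the sources used here, and other cells of the liver may carry the transcript, so this value neither checks nor contradicts the labels. Clec4g, the lectin gene of sinusoidal endothelium from which the driver was built, fell by 0.92 ± 0.23 (SE; adjusted p = 0.018), in 10 of 10 knockout livers relative to the control mean of their run. That call was lost when the run term was left out (adjusted p = 0.053).

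**Figure D1:**
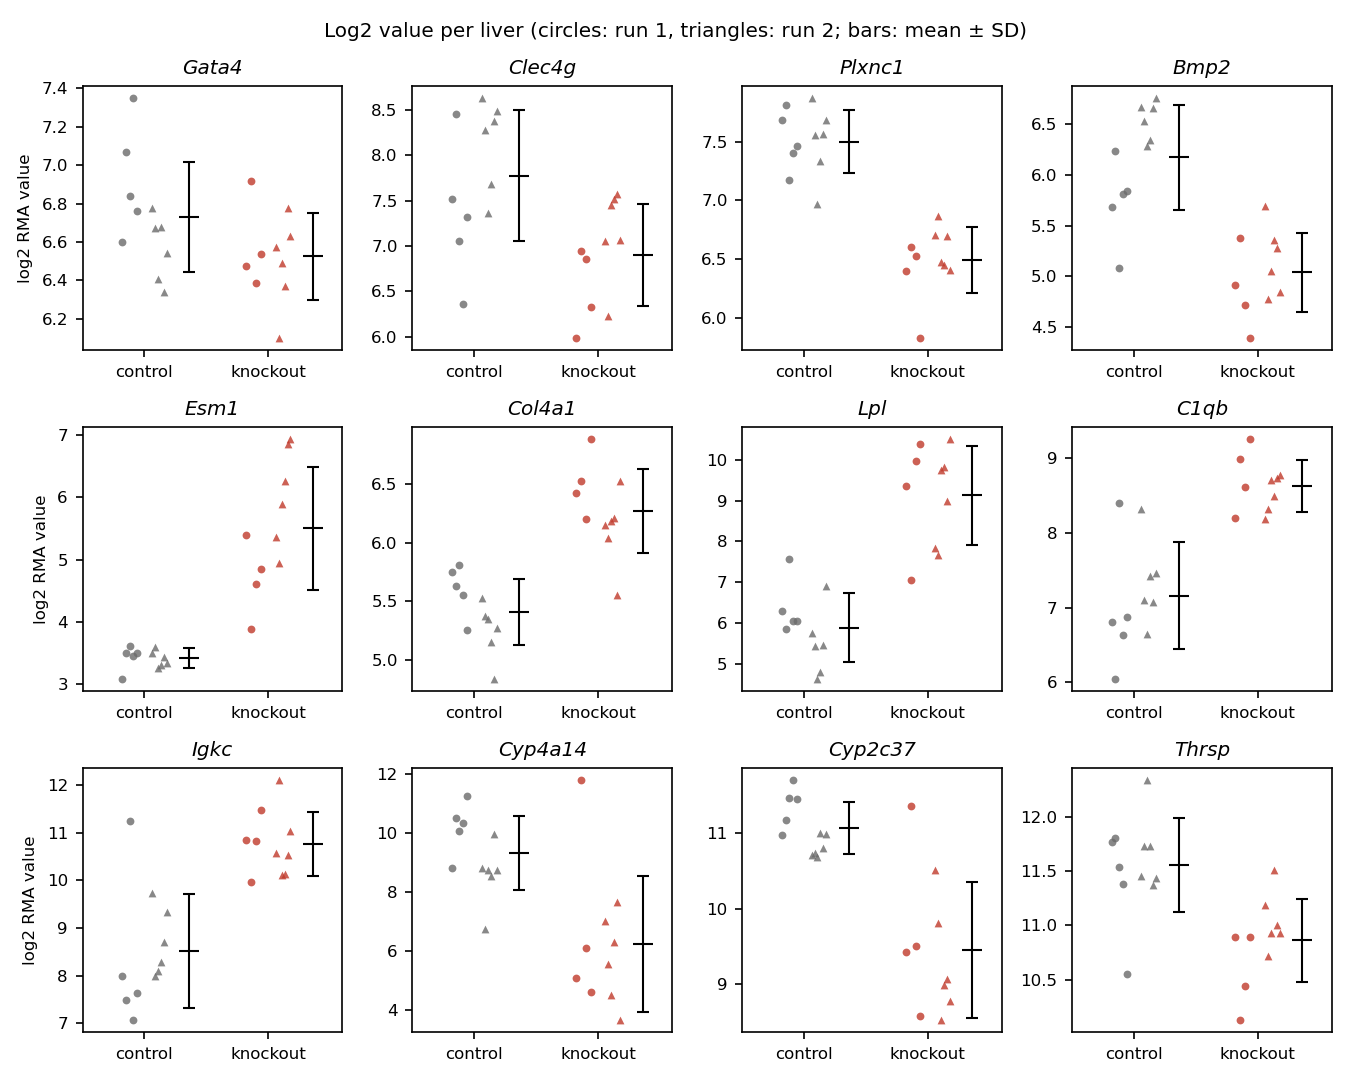
Log2 RMA value of 12 genes in each liver (control in grey, n = 11; knockout in red, n = 10; circles run 1, triangles run 2), with the mean and SD of each group as a bar. Plxnc1 did not overlap between genotypes (highest knockout 6.87, lowest control 6.97), nor did Esm1 (lowest knockout 3.89, highest control 3.61), while Gata4 overlapped widely.

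Among the 10 largest rises, Lpl rose by 3.28 ± 0.42 (log2, SE; adjusted p = 1.94e-04), by 2.84 in run 1 and 3.61 in run 2. Robo1 rose by 2.60 ± 0.40 (adjusted p = 9.22e-04) and Scd2 by 2.53 ± 0.47 (adjusted p = 0.0038), each in 10 of 10 knockout livers. Cib3, which encodes a calcium-binding protein, rose by 2.63 ± 0.61 (adjusted p = 0.013) in 8 of 10 knockout livers, with values from 4.13 to 9.54 among them. The neutrophil granule gene Ngp rose by 2.68, an immunoglobulin kappa variable (Igkv) gene by 2.55, the kappa constant gene Igkc by 2.24 and the acute phase protein gene Orm2 by 2.33. The call of Orm2 was lost without knockout replicate 3 or 4 (adjusted p = 0.057 and 0.051). Trappc5, a subunit of a vesicle tethering complex, rose by 2.85 ± 0.13 with the smallest adjusted p of any gene (2.06e-11), and Cd209a, a lectin of dendritic cells, rose by 2.43 ± 0.27 (adjusted p = 6.28e-05). Trappc5 and Cd209a are each the second measured gene away from Clec4g on their side of it, and 5 other genes among the 20 nearest to Clec4g were also higher.

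**Figure D2:**
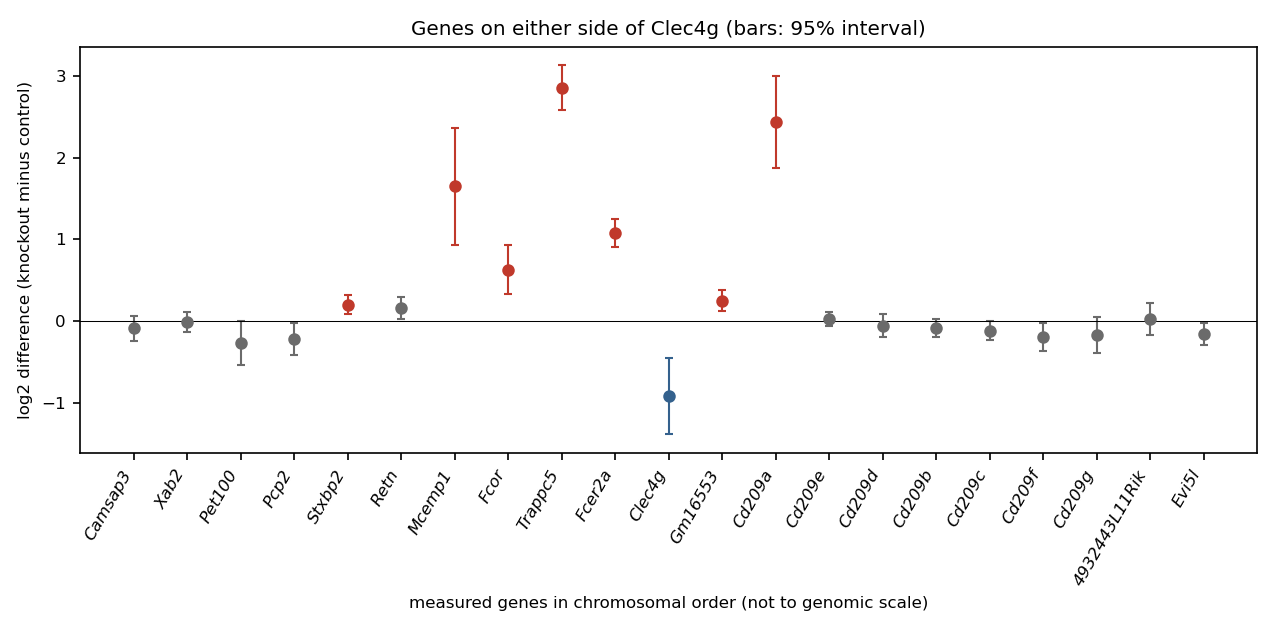
Genotype difference (log2, knockout minus control, n = 10 and 11) of Clec4g and of the 10 nearest measured genes on each side, in chromosomal order and not to scale, with 95% intervals; red marks genes that were higher, blue lower and grey those that did not pass. Trappc5 (2.85) and Cd209a (2.43) stand above their neighbours, and Clec4g lies at -0.92.

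Among the 10 largest falls were genes of cytochromes P450 and sulfotransferases, enzymes that modify lipids, steroids and drugs. Cyp4a14 was 8.03-fold lower (log2 difference -3.00 ± 0.70, SE; adjusted p = 0.013), but 1 knockout liver, replicate 2, had the highest value of all 21 (11.8, against 3.65 to 7.67 in the other knockout livers), and without it the log2 difference was -3.61. Cyp4a10 fell by 2.28 ± 0.63 (adjusted p = 0.032), a call lost without any 1 of 6 livers, where the adjusted p reached 0.059. Sult2a3 fell by 2.27 ± 0.44, Sult2a8 by 1.70 ± 0.40 and Sult2a5 by 1.63 ± 0.26. Cyp2c50 fell by 1.70 ± 0.37 and Cyp2c37, a pericentral cytochrome P450 gene, by 1.58 ± 0.26. Rgs16, a regulator of G protein signalling, fell by 1.99 ± 0.51, with -0.84 in run 1 and -2.84 in run 2. Mme, the gene of the peptidase neprilysin, fell by 1.55 ± 0.41 and the succinate receptor gene Sucnr1 by 1.42 ± 0.23. Of the 73 genes named here that passed the test, each moved in the direction of its mean in at least 8 of 10 knockout livers, and 54 did so in all 10. Their selection on these same livers favours such counts.

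Sinusoidal endothelial markers, which belong to fenestrated scavenging vessels, were lower with the preset correlation, and markers of continuous capillaries were higher. Whole liver does not separate a change within endothelial cells from a change in the share of vessel types or in other cells that express these genes, and this was not tested. Of 22 measured sinusoidal endothelial markers, 10 fell and none rose, with a median log2 difference of -0.34; adjusted over the list alone, 13 fell and 1 rose. Plxnc1 (a plexin receptor) fell by 1.01 ± 0.12 (SE; adjusted p = 7.16e-05), Bmp2 (the growth factor that drives hepcidin in hepatocytes) by 1.17 ± 0.15 (adjusted p = 1.85e-04) and F8 (coagulation factor VIII) by 0.77 ± 0.13 (adjusted p = 0.0015). The list passed the set test (adjusted p = 3.12e-08), but not when the correlation among its genes was estimated (adjusted p = 0.12 with an estimated correlation). Of 20 measured continuous endothelial markers, 10 rose and none fell (13 rose adjusted over the list alone), with a median of 0.38, and this list passed both ways (adjusted p = 7.16e-10, and adjusted p = 0.035 with an estimated correlation). Esm1, which marks sprouting and injured endothelium, rose by 2.05 ± 0.25 (adjusted p = 1.71e-04), Col4a1, a basement membrane collagen, by 0.88 ± 0.11 (adjusted p = 1.71e-04) and Plvap, the protein of fenestral diaphragms, by 0.86 ± 0.12 (adjusted p = 3.49e-04). The list score was above the highest control in 10 of 10 knockout livers.

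Markers common to all endothelium showed no joint shift. Of 21 measured, Eng rose by 0.48 ± 0.13 (SE), Ptprb fell by 0.56 ± 0.11 and Nos3, the endothelial nitric oxide synthase, fell by 0.43 ± 0.08. Adjusted over the list alone, 2 rose and 2 fell. The list had a median of 0.073 and an adjusted p of 0.29. The call of Eng was lost without any 1 of 5 livers (adjusted p up to 0.057). Angiocrine factors, the secreted signals of endothelium, had 3 of 25 members higher and 1 lower (7 and 2 adjusted over the list alone). Esm1 and Apln, a capillary tip cell peptide (0.37 ± 0.08), rose and Bmp2 fell. Esm1 and Apln were below the array median of 3.75 in controls (3.42 and 2.76). The list median was 0.097, it was -0.011 in run 1 and 0.088 in run 2, and the list passed with the preset correlation (adjusted p = 0.017) but not otherwise in 1 direction (adjusted p = 0.18 with an estimated correlation, 0.052 in fry).

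Lists of genes of the perisinusoidal matrix and its cells were higher with the preset correlation and did not pass with an estimated one. Of 27 measured myofibroblast and fibrillar matrix genes, 9 rose and none fell (13 rose adjusted over the list alone), with a median of 0.34 (adjusted p = 1.32e-09, and adjusted p = 0.13 with an estimated correlation). The receptor gene Pdgfra rose by 0.83 ± 0.20 (SE), the proteoglycan gene Bgn by 0.71 ± 0.13 and the collagen gene Col6a1 by 0.53 ± 0.11. Markers of quiescent stellate cells had 7 of 21 members higher and none lower (8 adjusted over the list alone). The median of this list was 0.14 (adjusted p = 1.78e-04, and adjusted p = 0.14 with an estimated correlation). Cygb, a globin of stellate cells, rose by 0.96 ± 0.15 (adjusted p = 8.75e-04), the pericyte gene Rgs5 by 0.79 ± 0.16 and the receptor gene Pdgfrb by 0.59 ± 0.12. Among 23 basement membrane genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), led by Nid1, the linker protein nidogen (1.47 ± 0.25; adjusted p = 0.0019), and Col4a2 (0.63 ± 0.08; adjusted p = 2.81e-04). The basement membrane list had a median of 0.067 and a mean of 0.23 (adjusted p = 2.06e-04, and adjusted p = 0.13 with an estimated correlation). Control replicate 3 had the highest control score for monocyte markers (0.58, against 0.29 to 1.63 in knockout livers), and 981 genes were higher and 1116 lower without it. Its matrix score (0.63) was above those of 9 of 10 knockout livers, and it was also the highest control for basement membrane (0.21), Kupffer cell (0.84), B cell (0.80), interferon (0.57) and acute phase (0.59) genes, so these lists overlapped between genotypes.

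**Figure D3:**
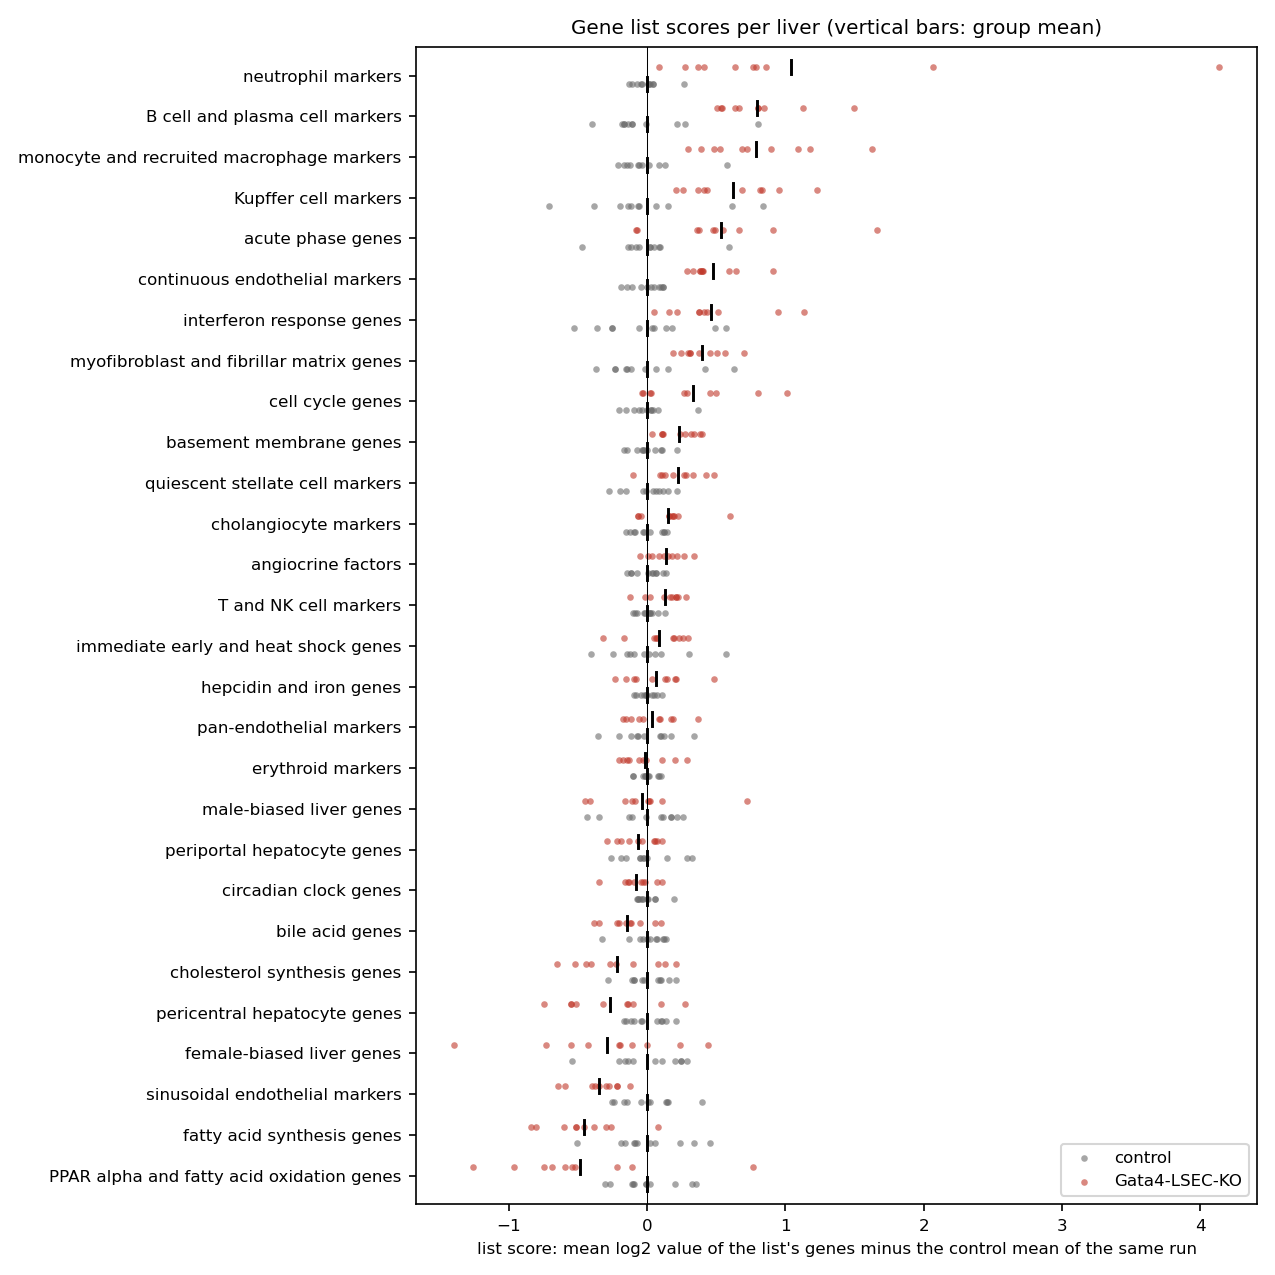
Score of each of 28 gene lists in each liver (control in grey, n = 11; knockout in red, n = 10), as the mean log2 value of its genes minus the control mean of the same run, with group means as vertical bars. Continuous endothelial scores ran from 0.29 to 0.91 in knockout livers and reached 0.12 in controls; neutrophil scores ran from 0.086 to 4.13 in knockout livers.

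Hepatocyte genes of the pericentral zone were lower as a list with the preset correlation, and those of the periportal zone had no net shift past the threshold. Of 24 measured pericentral genes, 7 fell and none rose (8 fell adjusted over the list alone), with a median of -0.22 (adjusted p = 4.13e-05, and adjusted p = 0.19 with an estimated correlation). Cyp2c37 led the fall, Cyp1a2, a caffeine-metabolising enzyme, fell by 0.81 ± 0.15 (SE; adjusted p = 0.0033) and Cyp27a1, the sterol 27-hydroxylase, by 0.38 ± 0.08. Of 23 periportal genes, 1 fell, G6pc, the glucose-6-phosphatase of gluconeogenesis (-0.58 ± 0.12; adjusted p = 0.006), also the only one adjusted over the list alone. The periportal median was -0.045 and the list did not pass (adjusted p = 0.46).

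Lists of lipid and bile acid genes were lower with the preset correlation and did not pass with an estimated one. Of 20 fatty acid synthesis genes, 5 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.47 (adjusted p = 7.10e-06, and adjusted p = 0.13 with an estimated correlation). Malic enzyme Me1 fell by 0.96 ± 0.15 (SE; adjusted p = 0.0013), the lipogenic regulator Thrsp by 0.71 ± 0.15 and the pyruvate kinase gene Pklr by 0.67 ± 0.16. The median was -0.10 in run 1 and -0.78 in run 2, a difference that passed its own test with the preset correlation (adjusted p = 0.002) but not with an estimated correlation (adjusted p = 0.98). Fatty acid oxidation genes under PPAR alpha had 4 of 25 members lower and none higher (7 lower and 1 higher adjusted over the list alone), with a median of -0.29 (adjusted p = 7.82e-05, and adjusted p = 0.31 with an estimated correlation); the peroxisomal thiolase gene Acaa1b fell by 0.67 ± 0.16 beside Cyp4a14 and Cyp4a10. Knockout replicate 2 had a score of 0.77 for this list, above the highest control (0.35), and the other 9 knockout livers ran from -1.26 to -0.11. Bile acid genes had 6 of 23 members lower and none higher (9 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 7.56e-04, and adjusted p = 0.12 with an estimated correlation). Nr1h4, the bile acid receptor FXR, fell by 0.39 ± 0.07 and Slc27a5, a bile acid ligase, by 0.29 ± 0.06. Cholesterol synthesis genes had 2 of 20 members lower, Pmvk (-0.65 ± 0.17) and Hsd17b7 (-0.48 ± 0.14), and none higher (3 lower adjusted over the list alone). Both calls were lost without single livers, 4 of them for Pmvk and 13 for Hsd17b7 (adjusted p up to 0.056 and 0.07). The cholesterol list median was -0.20 (adjusted p = 0.0043, and adjusted p = 0.36 with an estimated correlation), and Fdps had a difference of -0.66 ± 0.22 that did not pass (adjusted p = 0.073).

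Lists of monocyte and B cell markers were higher with either correlation, and Kupffer cell markers with the preset one. Of 18 monocyte and recruited macrophage markers, 8 rose and none fell (13 rose adjusted over the list alone), with a median of 0.73, 0.41 in run 1 and 0.96 in run 2 (adjusted p = 5.58e-11, and adjusted p = 0.035 with an estimated correlation). Cd52, a leukocyte surface glycoprotein, rose by 1.62 ± 0.27 (SE, adjusted p = 0.0016). The antigen presentation genes H2-Ab1 and Cd74 rose by 1.41 ± 0.26 and 1.30 ± 0.20. Neither leukocyte nor antigen presentation genes are confined to monocytes, so these members do not tell monocytes from B cells, whose markers also rose. Cd9, which rose by 0.93, is on this list and on the continuous endothelial list. Of 20 Kupffer cell markers, 9 rose and none fell (11 rose adjusted over the list alone), with a median of 0.61 (adjusted p = 3.37e-10, and adjusted p = 0.13 with an estimated correlation). The complement genes C1qb and C1qa rose by 1.46 ± 0.24 and 0.79 ± 0.16, and the heme oxygenase gene Hmox1 by 1.12 ± 0.15 (adjusted p = 2.81e-04). B cell and plasma cell markers had 8 of 18 members higher and none lower (10 adjusted over the list alone), with a median of 0.37 (adjusted p = 4.15e-09, and adjusted p = 0.035 with an estimated correlation). Beside Igkc, the heavy chain genes Ighg1 and Igha rose by 2.20 ± 0.40 and 1.74 ± 0.28. Immunoglobulin genes have near-identical relatives whose transcripts the probes may share, so the values of single members, the Igkv gene above included, are uncertain.

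T cells, NK cells and neutrophils, the lymphocytes and granulocytes of the liver, were followed by their own markers. Of 23 measured T and NK cell markers, 4 rose and none fell (6 rose and 2 fell adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0026, and adjusted p = 0.14 with an estimated correlation). The T cell receptor constant gene Trac rose by 0.66 ± 0.19 (SE), the interleukin receptor gene Il2rb by 0.39 ± 0.09 and Cd3e by 0.26 ± 0.07. Each was dim in controls (3.29, 3.56 and 3.69, with an array median of 3.75), so their values may lie near background. The call of Trac was lost without any 1 of 11 livers (adjusted p up to 0.073) and that of Cd3e without any 1 of 4 (up to 0.058). Neutrophil markers had the largest median of the lists, 1.04, with list scores from 0.086 to 4.13 among knockout livers, the highest in replicate 6. Yet 2 of 18 passed, Ngp and Lcn2, an iron-binding lipocalin (1.94 ± 0.39), and 6 rose adjusted over the list alone. Lcn2 is also on the acute phase list and had a log2 value of 9.58 in controls, against 3.54 for Ngp, so its rise is not specific to neutrophils. Mpo, the myeloperoxidase gene, had a difference of 1.52 ± 0.48 with an SD of 1.68 among knockout livers (adjusted p = 0.059). The neutrophil list passed with the preset correlation (adjusted p = 9.41e-08) and in fry (adjusted p = 0.048), but not with an estimated correlation (adjusted p = 0.19 with an estimated correlation), and its genes had an estimated correlation of 0.70.

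Lists of acute phase, interferon and cell cycle genes were higher with the preset correlation and did not pass with an estimated one. Of 25 acute phase genes, 9 rose and none fell (14 rose adjusted over the list alone), with a median of 0.37 (adjusted p = 2.74e-09, and adjusted p = 0.13 with an estimated correlation); Lbp, the lipopolysaccharide-binding protein gene, rose by 0.68 ± 0.12 (SE) and the heme carrier gene Hpx by 0.41 ± 0.08. Interferon response genes had 6 of 31 members higher and none lower (16 higher adjusted over the list alone), with a median of 0.35 (adjusted p = 9.28e-11, and adjusted p = 0.14 with an estimated correlation). The chemokine gene Cxcl9 rose by 1.46 ± 0.26, the transcription factor gene Irf7 by 1.12 ± 0.27 and the antiviral enzyme gene Oas2 by 0.49 ± 0.12. Of 35 cell cycle genes, 2 rose, Cdk1 (0.78 ± 0.20) and the survivin gene Birc5 (0.30 ± 0.08), and 9 rose adjusted over the list alone. Cdk1 and Birc5 were dim in controls (3.51 and 2.83, with an array median of 3.75), so their values may lie near background. The cell cycle list had a median of 0.30 (adjusted p = 1.49e-08, and adjusted p = 0.17 with an estimated correlation), and cyclin D1 (Ccnd1) had a difference of 0.62 ± 0.19 (adjusted p = 0.051). The highest cell cycle scores were those of knockout replicates 6 (1.01) and 3 (0.80), which also had the highest neutrophil scores (4.13 and 2.07). Replicate 6 had the highest acute phase score (1.66) and replicate 10 the highest interferon score (1.14). Of 17 cholangiocyte markers, 1 rose, the progenitor marker Prom1 (0.96 ± 0.24), and 2 rose adjusted over the list alone; Sox9, the biliary transcription factor, had a difference of 0.57 ± 0.18 (adjusted p = 0.06). The cholangiocyte median was 0.075 (adjusted p = 0.023, and adjusted p = 0.31 with an estimated correlation), and the list did not pass without knockout replicate 7 (adjusted p = 0.12).

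Several lists had no net shift to 1 side past the threshold. In the mixed form of the rotation test fry, which takes changes in either direction, the lists below passed, from female-biased genes (adjusted p = 5.38e-07) to immediate early genes (adjusted p = 0.018), except erythroid markers (adjusted p = 0.43). Erythroid markers had none of 16 members past the limma test over all genes and none adjusted over the list alone. The erythroid median was -0.025 while the set test pointed up (adjusted p = 0.92), and Slc4a1, the red cell anion exchanger, had a difference of 0.31 ± 0.14 (SE; adjusted p = 0.20). Hepcidin and iron genes had 1 of 23 members lower, Bmp2, also adjusted over the list alone, with a list median of 0.075 (adjusted p = 0.19). Circadian clock genes had none of 20 past either threshold (median -0.12, adjusted p = 0.32); Arntl, the clock activator, had a difference of -0.38 ± 0.14 (adjusted p = 0.10). Of 27 immediate early and heat shock genes, 1 rose, Ier3 (0.50 ± 0.13), also adjusted over the list alone (median 0.082, adjusted p = 0.063). The call of Ier3 was lost without knockout replicate 3 or control replicate 9 (adjusted p = 0.052 for each). Male-biased liver genes had 1 of 19 higher, the complement gene C6 (1.86 ± 0.29; adjusted p = 9.45e-04), with 1 higher and 1 lower adjusted over the list alone (median -0.069, adjusted p = 0.65); Nudt7, a peroxisomal hydrolase gene, had a difference of -0.37 ± 0.12 (adjusted p = 0.057). Female-biased genes had 5 of 23 lower and 2 higher (7 and 4 adjusted over the list alone), with Sult2a2 (-0.46 ± 0.11) beside Sult2a3 and Sult2a5 among the former and Prom1 among the latter (median -0.21, adjusted p = 0.18). Xist ranged from 10.45 to 10.97 on the arrays and 3 Y-linked genes from 2.32 to 2.98, so no array differed from the others in sex-linked transcripts by more than 2 log2 units.

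Of the 28 lists, 20 passed the set test with the preset correlation of 0.01, and 3 of these passed with an estimated correlation: continuous endothelium, monocytes, and B and plasma cells. When the livers were split at random into groups of the same sizes, the preset test passed a median of 8 lists while the median count of single genes was 0, so a list call by the preset test alone carries less weight than the counts of its genes.

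The genotype difference was compared between the runs of livers. Across all measured genes the differences in run 1 and run 2 had r = 0.489 (genes are not independent replicates). Of the 1864 genes that passed over all livers, 1862 had the same direction in each run, a count that the selection of genes on both runs favours and that does not measure how alike the runs were; r across them was 0.884. The exceptions, named because they were so few, were Max (-0.03 in run 1 and 0.55 in run 2) and Mcat (0.02 and -0.54). Within run 1 alone, limma passed 3 genes, Trappc5 (2.91), Fcer2a (0.99) and Abcg2 (-1.04). Of these, Trappc5 and Fcer2a are among the 20 measured genes nearest to Clec4g. Within run 2 alone, 552 genes were higher and 735 lower. The genotype difference itself differed between runs for 8 genes, 2606 at an unadjusted p below the threshold. Between the runs, whatever the genotype, 491 genes were higher and 553 lower in run 2.

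**Figure D4:**
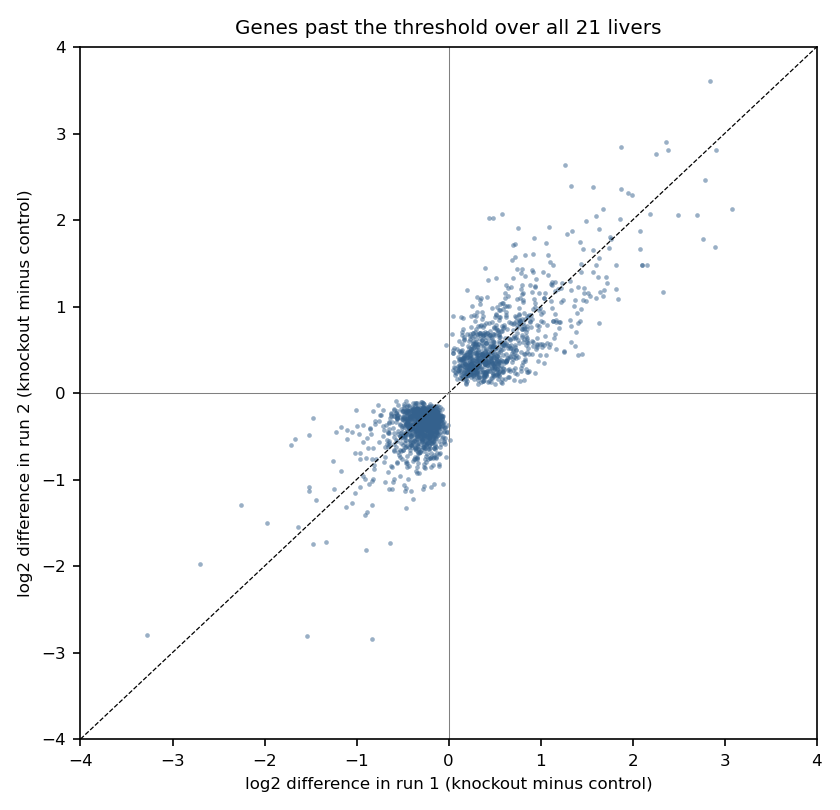
Genotype difference (log2, knockout minus control) of each of the 1864 genes past the threshold over all 21 livers, within run 1 on the horizontal and run 2 on the vertical axis, with the line of equal values dashed. Nearly all points share their sign in both runs (1862 genes).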

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

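The test of genes around Clec4g and the comparisons of Trappc5 with immune and neutrophil markers by size were chosen after their results were seen, as were the rank correlation of Trappc5 with the monocyte score and its value without 2 livers, and the comparison of pan-endothelial, erythroid and Kupffer cell medians; the other tests of this part were set before.

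Among 81 genes, the knockout group of 10 held an outlying value in 8, where chance flags about 1 in 20 groups. Cd52 was high in knockout replicate 6 (7.74), Cdk1 in replicate 3 (5.76), Slc4a1 in replicate 9 (4.75), Cyp27a1 in replicate 5 (10.9) and Cyp4a14 in replicate 2 (11.8). Cd3e was low in replicate 5 (3.49), Plxnc1 in replicate 4 (5.82) and Sult2a8 in replicate 4 (5.55). Replicates 4 and 5 each held 2 of these values, and no other liver more than 1.

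The genotype difference changed between the runs in 8 genes, given here as run 2 minus run 1 on the log2 scale. It was lower in run 2 for the clock gene Per1 (-1.41), Ppp1r15a (-1.04), Ppp1r35 (-0.94) and Tob1 (-0.77), and higher for Chchd4 (1.20), Map3k5 (1.09), Trmt1l (0.70) and Rnf20 (0.65). Fatty acid synthesis genes also differed by the preset test (adjusted p = 0.00197), but not with an estimated correlation (adjusted p = 0.98). Of 100 assignments of the run within each genotype, 2, the real one included, gave as many as 8 genes. The other of these gave 255, and the cause of that count was not tested.

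Of the 20 measured genes nearest to Clec4g, 7 were higher in knockout livers (Stxbp2 0.20, Mcemp1 1.65, Fcor 0.63, Trappc5 2.85, Fcer2a 1.08, Gm16553 0.25 and Cd209a 2.43), a count reached by 0.234% of such windows around other genes, while the 6 other Cd209 genes measured next to Cd209a did not pass; these names were chosen after their values were seen. A larger share of Kupffer cells, monocytes, T cells or B cells was weighed as the whole source of the Trappc5 rise. The highest of the 4 median marker differences was 0.73, below the 95% interval of Trappc5 (2.58 to 3.13). A list median takes in dim markers, such as Trac (3.29 in controls), so it sets no upper limit. Igkc, the highest of the 79 markers compared, rose by 2.24, with a 95% interval up to 3.09 that overlaps that of Trappc5. The medians thus cannot decide on B and plasma cells. Trappc5 did not follow the monocyte score across the 10 knockout livers (r = -0.467, 95% interval -0.848 to 0.230, permutation p = 0.171). By rank, rho was 0.030 (permutation p = 0.946). The value of r rested on 2 livers and was 0.460 without them. For a larger share of neutrophils as the whole source, whose list median was 1.04, the 3 of 18 markers above the median signal in controls were compared. Over the 10 knockout livers, Trappc5 rose by a median of 2.77 more (95% interval 1.72 to 2.95) than the median of these 3 markers. It rose by 0.87 more (0.21 to 1.74) than the highest of them, Lcn2. Knockout replicate 6, with the highest neutrophil score, went the other way (Lcn2 4.2, Trappc5 2.1). Ngp, below that signal in controls, rose by 2.68, within the interval of Trappc5. The comparison cannot decide on neutrophils, since it kept only markers with signal in control liver. Lcn2, at 9.58 in controls, is also on the acute phase list, so its rise need not follow neutrophils. Sequence carried along with the driver transgene, as a large genomic insert holding these neighbours would be, may account for the block if the controls lacked the driver (not given in the sources used here), in which case every genotype difference is that of Gata4 loss and driver together; a change of Trappc5 within resident cells stays open as untested.

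Few genes passed within run 1 alone: 3, against 1287 in run 2. Of 90 subsets of run 2 with 5 controls and 4 knockout livers, 1 gave as few (median 195.5, lowest 3, highest 2410). Fewer arrays thus seldom gave so few calls among the livers of run 2. The subsets overlap and come from the same 12 livers, so they cannot exclude fewer arrays as the whole cause. A larger spread in run 1 stays open by the limits set, although the ratio of residual SDs was 1.01 (0.933 to 1.07 over left-out arrays). A smaller genotype difference in run 1 may contribute, with a ratio of 0.843 (0.719 to 0.961). The runs cannot be told apart from cohorts of animals, which the labels do not describe.

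Immune markers were higher and hepatocyte metabolic genes lower in knockout livers with the preset correlation, but with an estimated one the Kupffer (adjusted p = 0.129), T and NK (0.144), neutrophil (0.187), pericentral (0.187), fatty acid synthesis (0.129) and fatty acid oxidation (0.309) lists did not pass. A lower share of hepatocytes would lower hepatocyte genes at large, but 24 secreted and periportal genes with mean log2 values under 12 had a median difference of -0.0089 (95% interval -0.126 to 0.092), above the pericentral (-0.22) and fatty acid synthesis (-0.47) medians. A loss of share large enough to give those medians was thus not seen in the median of these 24 genes. The interval came from 10000 resamplings of the genes and does not take in the spread between livers. It therefore cannot exclude a lower share, and a smaller loss stays open. Pan-endothelial and erythroid medians were 0.073 and -0.025 against 0.61 for Kupffer cells. These medians cannot decide on the share of hepatocytes. Pan-endothelial markers moved both ways, and Slc4a1, the erythroid marker with the lowest p, was dim (3.25 in controls, with an array median of 3.75). The number of lists past the threshold did not rest on 1 liver (19 to 21 without each in turn), but the cholangiocyte list lost its call without knockout replicate 7 (adjusted p = 0.118) and the immediate early list gained one without control replicate 4, 6 or 7 or knockout replicate 5 or 8. A change of the hepatocytes' own transcription together with more immune cells may account for the pattern, and the order of these changes was not tested.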

How the results depend on the processing

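The alternative without the 2 least correlated arrays, control replicates 3 and 4, and the split counts per list were chosen after seeing the data. The 834 higher and 1030 lower genes stayed within 1.5 times these counts without the run term, after requantiling, median centring, with a trend and robust prior, with array weights, without dim genes and without those 2 arrays (712 to 871 higher, 832 to 1109 lower). Within run 1, 2 genes were higher and 1 lower; within run 2, 552 were higher and 735 lower. Without 1 array, higher genes numbered 565 (control replicate 8 out) to 981 (control replicate 3 out), and lower genes 629 (control replicate 8 out) to 1471 (control replicate 1 out), with 661 lower without control replicate 9. The difference of Gata4 stayed below 0 and outside the threshold under each alternative run, from -0.34 within run 1 to -0.08 within run 2. The genotype by run count was 5 with the trend and robust prior.

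Of 100 splits of the arrays, only the real one gave as many as 834 higher genes (1 of 100, highest other 1) or 1030 lower genes (1 of 100, highest other 1). Of 100 splits into 9 and 12 arrays, only the real runs gave 1044 genes (1 of 100, highest other 1). Random splits thus did not come near these counts, although 100 splits cannot show a share below 1 of 100. The splits took all livers as exchangeable, also across runs. For gene lists, 2 of 100 splits gave 20, the real one and 1 other, and the other splits passed a median of 8. Of the 20 lists, 9 had a p reached by fewer than 5 of the 100 splits; continuous endothelium, monocytes, B and plasma cells and bile acid genes had one reached by no other split.

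With an estimated correlation 3 lists passed. The adjusted p was 0.122 for sinusoidal endothelium and for bile acid genes, 0.129 for Kupffer, matrix, basement membrane and fatty acid synthesis genes, 0.132 for acute phase, 0.144 for stellate, T and NK and interferon genes, 0.168 for cell cycle, 0.18 for angiocrine, 0.187 for neutrophil and pericentral, 0.309 for cholangiocyte and PPAR alpha, and 0.361 for cholesterol genes. This setting takes in the correlation among the genes of a list, but that is not its only difference from the preset one. Circadian genes had an estimated correlation of 0.0082, below the preset 0.01. Their unadjusted camera p was nonetheless higher, 0.296 against 0.289. How much of each change the correlation accounts for was not tested. With fry, PPAR alpha and angiocrine genes had 0.0523, cholangiocyte 0.125 and cholesterol 0.0923. Within run 1, angiocrine genes had 0.211, cholangiocyte and fatty acid synthesis 0.234, and immediate early genes 0.00291. Without dim genes, T and NK markers had 0.128, angiocrine 0.232 and cholangiocyte 0.0571. Cholesterol genes had 0.0631 with array weights. For these the cause was not tested. Directions turned for lists that did not pass: erythroid genes with array weights (0.847), fry (0.864), within run 1 (0.440), without dim genes (0.635) and without the 2 arrays (0.993); periportal genes within run 1 (0.743); male-biased genes within run 2 (0.917) and without dim genes (0.998). Without single arrays, erythroid genes ranged from 0.569 to 0.977 and turned in 7 cases, cholangiocyte genes from 0.0106 to 0.118 (knockout replicate 7 out), and immediate early genes from 0.0078 (control replicate 6 out) to 0.163.

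Replicate numbers are shared between genotypes but do not pair the animals: deviations of same-numbered livers correlated from -0.061 to 0.192, 3 of 10 over 0.1, and 0 controls correlated best with their own number. With the number as a replicate block in place of the run, 703 genes were higher and 714 lower (1223 of these 1417 shared with the 1864), cholesterol genes had an adjusted p of 0.0966, and 8 named genes did not pass (Trac, Ier3, Eng, Cd3e, Hsd17b7, Pmvk, Pklr and Clec4g).

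Single genes lost their call without 1 array in these cases: Cyp4a10 (knockout replicates 1, 3, 4, 7 and 10, control replicate 9), Orm2 (knockout 3 and 4), Ier3 (knockout 3, control 9), Cd3e (knockout 3 and 4, control 2 and 4), Pmvk (knockout 3 and 7, control 8 and 9), Eng (knockout 3, 4 and 10, control 8 and 9), Trac (11 arrays) and Hsd17b7 (13 arrays). Of the 80 named genes besides Gata4, 1 lost its call without the run term (Clec4g), 3 with array weights (Cd3e, Hsd17b7, Pmvk), 4 without the 2 arrays (Ier3, Eng, Pmvk, Cyp4a10), 21 within run 2 and 72 within run 1. Scanner signals were not used, so how far dim genes lie above background was not measured.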

Other observations

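The family test was not among the choices made before the data were examined; it took in every symbol stem with at least 15 measured genes, whatever the outcome, and the members named were chosen after their values were seen. The tests around Gata4 and of the list scores were set before their results were seen.

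Families of enzymes of drug and steroid handling held a larger share of lower genes than the other named genes did, although most of their members did not pass. Of 104 Cyp genes, 19 were lower and 1 higher in knockout livers (adjusted p = 4.99e-06, Fisher's exact test over 155 families in both directions), and beside those already named Cyp3a25 fell by 1.32 ± 0.17 (SE), Cyp2c54 fell by 1.27 ± 0.34 and Cyp3a59 fell by 1.10 ± 0.24. Of 21 Sult genes, 6 were lower (adjusted p = 0.011), Sult1b1 (-0.81 ± 0.18) and 5 of the Sult2a group, among them Sult2a1 (-0.85 ± 0.22). Of 18 Ces genes, the carboxylesterases, 5 were lower (adjusted p = 0.032), from Ces1g (-1.18 ± 0.19) to Ces2a (-0.54 ± 0.12). These families hold close relatives whose probes may share transcripts, so counts of single members, 19 for Cyp among them, may overstate independent changes. Of 24 Btbd genes, 6 were lower (adjusted p = 0.020), 5 of them Btbd35f genes, also near-identical relatives.

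Immunoglobulin variable families held a larger share of higher genes than the other named genes did, although most of their members did not pass. Of 102 Igkv genes, 27 were higher and 1 lower (adjusted p = 1.09e-13, Fisher's exact test), and of 94 Ighv genes, 19 were higher and 1 lower (adjusted p = 2.03e-07). These are also near-identical relatives whose probes may share transcripts, so the counts may overstate independent changes. Cd-numbered genes, a mixed set of surface proteins, had 18 of 97 higher and 1 lower (adjusted p = 1.53e-06); among them were Cd5l of Kupffer cells (1.16 ± 0.26), Cd34 of capillaries (0.77 ± 0.11) and Cd79a of B cells (0.57 ± 0.14), while Cd1d1, which presents lipids to NKT cells, fell by 0.65 ± 0.08.

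It was asked whether sequence around the floxed Gata4 allele carried differences along, as it may when the allele comes from another strain. Of the 100 measured genes nearest to Gata4, 11 passed in either direction, against a median of 7 in such windows, and 14.4% of windows held as many, so no excess was found.

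A further hypothesis was that some list scores follow each other across livers, tested for 4 pairs within each genotype (8 relations). Across the 10 knockout livers the matrix score had r = 0.556 with the monocyte score (permutation p = 0.0957, adjusted 0.245; rho = 0.636, permutation p = 0.0543) and r = 0.291 with the continuous endothelial score (permutation p = 0.429, adjusted 0.577; rho = 0.176, permutation p = 0.632). The monocyte score had r = -0.269 with fatty acid oxidation genes (permutation p = 0.454, adjusted 0.577; rho = -0.285, permutation p = 0.425) and r = 0.238 with fatty acid synthesis genes (permutation p = 0.505, adjusted 0.577; rho = 0.224, permutation p = 0.539). Without the 2 livers farthest from the median of the monocyte or continuous endothelial score these were 0.767, 0.121, -0.397 and 0.0485. None passed adjustment, so these relations stay open with 10 livers, and run 1 held too few knockout livers for a value of its own. Across the 11 controls the matrix score followed the monocyte score (r = 0.834, permutation p = 0.00225, adjusted 0.018; rho = 0.718, permutation p = 0.0165, adjusted 0.0661), a relation that rested on 2 livers, since r was 0.389 without them. The other 3 control relations did not pass by r; matrix with continuous endothelium had r = 0.691 (adjusted 0.0704) and rho = 0.791 (adjusted 0.0425), and r was 0.735 without the 2 farthest livers.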
